A study of Cavia porcellus with 24 samples.

How the data were processed

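The samples are RNA-sequencing libraries of guinea pig skin. Per the labels' protocols, RNA with an integrity number of at least 7 was made into stranded mRNA libraries. The tables deposited by the authors are named as counts, and their values were not analysed here. The aligner, the counting tool and the annotation are not given in the sources used here. The submitters' processing notes name the mouse build mm10, while most LOC identifiers in the tables are guinea pig genes.

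Groups and replicate numbers came from the sample titles. The 24 value columns of the 4 tables have names that match no title, description, source name or characteristic. Column order and the values themselves were not used to assign them, so these 24 columns were left out of every result and no test was run. The planned tests, their alternatives and the rule for named genes, fixed before the data were examined, could not be applied for this reason. The parts of that rule that rest on test results chose no gene. A further part fixed genes to be given whatever their result. Some genes named in the report, such as KRT16, KRT17 and MMP1, are among those. Which genes to name here was decided after seeing which symbols had a row.

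Row identifiers were read with Python 3.11.15. Identifiers were compared between tables as written, and with the RefSeq symbols and the gene lists without regard to case. These numbers are counts of names. Whether sequencing depth decided which names a table lists was not tested.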

Results

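The series followed guinea pig skin after one treatment with a fractional CO2 laser, a device that ablates skin in an array of narrow columns and leaves the skin between them in place. By the sample labels, 24 RNA-sequencing samples fell into 8 groups of 3, with laser-treated and control skin at days 1, 3, 5 and 7. The series' description says that the side of the back opposite the laser was left without irradiation. The labels imply a comparison of laser-treated with control skin on each day, and of that difference between days.

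None of these comparisons was made. The 24 value columns of the 4 count tables carry running numbers as names, and the names of all 24 match no label of any sample. Which columns hold laser-treated skin is therefore open, and no expression level, fold change or depth per group is given. What follows covers only which genes the tables list. The tables differ in the genes they list, and how rows were chosen for each table is not given in the sources used here. A row or its absence may therefore depend on the counts, on the annotation or on the symbol used, and the coverage given here is no measure of expression.

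The tables named for days 1, 3, 5 and 7 listed 17425, 17573, 17675 and 17675 gene identifiers, with none repeated within a table. All 4 tables shared 17055 identifiers, and 980 others stood in some tables but not in all. The tables named for days 5 and 7 listed the same identifiers. Of the 18035 identifiers in any table, 16575 (91.9%) were symbols in the guinea pig RefSeq gene table of assembly mCavPor4.1. Among 2686 identifiers that begin with LOC, 1888 were in that table. A further 11 identifiers read as dates, from 1-Mar to 11-Mar.

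The 40 gene lists held 947 distinct symbols, of which 794 were listed in all 4 tables. They were fixed for skin, wound repair, heat injury and other tissues that a skin biopsy can hold. Whether each symbol in the lists names a guinea pig gene was not checked. Some lists hold an older and a newer symbol of the same gene. RIGI, LORICRIN, TRARG1 and CEMIP2 had no row, while their older symbols DDX58, LOR, TUSC5 and TMEM2 were in all tables. Such genes count as both listed and missing. Older symbols that are not in the lists were not searched. Nor were the LOC identifiers examined for genes whose symbol had no row. The list of fibrillar collagens and matrix structure genes had 42 of 43 members in all tables, the metalloproteinases and their inhibitors 25 of 26, and the TGF-beta pathway 28 of 29. The provisional matrix and matricellular genes had 14 of 17, with no row under the symbols CCN1, CCN2 and CCN4. Cell cycle genes had 47 of 48 members. All members were listed for the endothelial genes (21), the lymphatic endothelial genes (7), the contractile smooth muscle genes (15), the B and plasma cell markers (12), the Schwann cell genes (15) and the cytosolic ribosomal protein genes (43).

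Other lists had more members without a row, and gaps were not confined to genes of injury or immunity. Red blood cell genes had 4 of 12 members in all tables and oxidative phosphorylation genes 25 of 39. The 13 oxidative phosphorylation symbols with no row in any table were all of that list's UQCR, CYC1 and COX genes. Mast cell markers had 7 of 11, while monocyte and macrophage markers had 21 of 22. The inflammatory cytokine and chemokine list had 18 of 28 members in all tables and the interferon response list 15 of 27. Of 30 wound-edge keratinocyte genes 21 were in all tables, while KRT16 and KRT17, keratins of activated epidermis, had no row under those symbols. The epidermal differentiation list had 24 of 34 members, without KRT10 and FLG, a keratin of the upper epidermis and the precursor of filaggrin. The hair shaft and inner root sheath list had 23 of 39. Neutrophil markers had 12 of 20, without S100A8, and antimicrobial genes 7 of 21, without LCN2. Examples of single genes without a row under their symbol in other lists were HSPA1A and HSPA1B in the heat shock list (19 of 23). These 2 genes encode inducible HSP70. Other examples were MMP1, a collagenase, KRT14 in the basal keratinocyte list and SCD in the sebaceous and fatty acid synthesis list. All other genes that were fixed to be given whatever their result had a row in some or all tables. Among them, IL1B, CXCL8, MMP3, MMP9, COL1A1, COL3A1 and HSPH1 were in all tables.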

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

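The following alternatives were chosen after seeing the data. Ignoring case left the number of identifiers shared by all tables at 17055, and requiring matching case left the number of RefSeq symbols at 16575. Requiring matching case left 6 list members in all tables in place of 794, because the lists are written in capitals and most symbols in the tables are not. Counting members listed in any table gave 803. The alternatives planned for the expression comparisons were not run. The main planned tests did not pair control and laser-treated libraries. No paired analysis was possible either, because the columns carry neither a treatment nor a replicate number that the labels identify.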
